A study of Caenorhabditis elegans with 2 samples.

How the data were processed

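UNC-3 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole late embryos of the nematode Caenorhabditis elegans. Per the labels, the strain carried an integrated transgene that expresses UNC-3 with a C-terminal GFP-FLAG tag in an unc-119 mutant background, chromatin was sonicated, and the precipitation used an antibody against GFP. The 2 libraries are biological replicates 1 and 2 of a single group, collected 4 h after synchronization by egg bleaching. There is no second condition, so the comparisons are between the replicates, between peaks and matched genomic positions, and between groups of genes.

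The authors deposited peak lists in the narrowPeak layout for the genome builds ce10 and ce11. Per the file headers in the accompanying notes, each replicate list was called on that replicate's alignment with a control alignment and holds peaks together with background, as input for the irreproducible discovery rate (IDR), a method that ranks peaks by their agreement between replicates. A pooled list of the same kind was called on both alignments together, and the optimal IDR-thresholded list was derived from the replicate lists and the pooled list. The signal value of each peak is the strength the authors' peak caller assigned to it, on a scale not given in the sources used here, and it was used only to rank and describe peaks. The deposited −log10 q-value was 1.87 for every peak of the IDR list in ce11 and was not used for ranking. Aligner, peak caller, IDR threshold and read depth are not given in the sources used here, and the control alignment was not analysed here. Depth is therefore unknown, and no interval that would need it is given. Intervals on shares of peaks or genes are exact Clopper-Pearson intervals at 95% and cover counting error only.

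Coordinates are 1-based in ce11, the build of the WBcel235 genome sequence, with Ensembl release 115 genes. The ce10 lists were used only where no genome sequence is needed. Peaks are called IDR peaks when they belong to the IDR list, of N = 754 peaks. The replicates were compared by the share of the N strongest replicate 1 peaks that overlapped one of the N strongest replicate 2 peaks by at least 1 bp, against 1000 random relocations within chromosomes (one-sided permutation test). Signal was compared across IDR peaks by Spearman's and Pearson's correlation of the strongest overlapping replicate peaks, on log2 values for Pearson's, with 100000 permutations of the pairing. The X share of nuclear peaks was tested with an exact binomial test against the X share of nuclear length. Promoters ran from 500 bp upstream to 100 bp downstream of any of 29326 protein-coding transcription start sites (TSSs), and shares were tested against 1000 relocations, two-sided. The COE palindrome TCCCNNGGGA was searched within 100 bp of each summit and in windows centred 1000 bp to either side. Shares of flanking windows average both sides. The exact McNemar test compared each summit window with the flanking window on a side drawn at random per peak with a fixed seed. Stronger and weaker peaks, split at the median signal, were compared with Fisher's exact test. Genes counted as having a peak when a summit lay from 2000 bp upstream to 500 bp downstream of a TSS. Each of 18 gene lists was tested against the other genes among 19985 protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists.

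These tests, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes unc-3 and unc-119, the nearest protein-coding gene of the 25 strongest IDR peaks, and members of the lists in order of peak signal. Of the 22 listed cholinergic motor neuron effectors, 21 matched the annotation; all members of the other lists matched. Comparisons with tRNA, snoRNA and snRNA genes, within 200 bp of a summit, and the restrictions to nuclear peaks or the extension to the whole pooled list were chosen after seeing the data. Peaks named because they carry the palindrome were also chosen after their values were seen.

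The procedures were tested on simulated data. Among 2000 random windows, some with a planted palindrome, 100% of the windows with it and 0% of the others were called. Random windows that held the palindrome by chance had been discarded beforehand. This checked only that the search works, not how often the palindrome occurs by chance. For the replicate overlap, 56.8% of 741 peaks were planted as shared and 59.7% were found. Among 19985 genes, every list of 50 genes with peaks planted at the TSSs of 15 was called at an unadjusted Fisher's exact p of 0.05. Of random lists, 3.0% were called. Most gene lists tested here were smaller, down to 6 genes, and the adjustment over lists was not simulated. Sensitivity for such small lists was therefore not tested. Alternatives covered the overlap rule, the number of peaks, the build, a stricter signal threshold, each replicate alone, removal of peaks within 50 kb of unc-3 and unc-119, other promoter and gene windows, a background matched on upstream gene-free length, and other motif definitions. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.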

Results

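UNC-3 is the C. elegans member of the COE (Collier/Olf/EBF) family of transcription factors and is known as a terminal selector of cholinergic motor neurons. Its binding was profiled with a GFP-tagged transgene in whole late embryos, in 2 biological replicates of 1 group, 4 h after synchronization. The replicate 1 list held 20517 peaks and the replicate 2 list 21474, background included, and the pooled list held 15515. After IDR thresholding 754 peaks remained in ce11, which were the 754 strongest peaks of the pooled list. Their signal, the value the authors' caller gave each peak, ran from 60.2 to 996.8 with a median of 84.6. Read depth is unknown. The control library and peaks of other factors were not analysed here, so peaks specific to UNC-3 were not separated from peaks shared with other factors or with the control.

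The first question was how far both embryo preparations gave the same sites. The strongest nuclear site, upstream of K12H4.5 on chromosome III, had a signal of 300.1 in replicate 1 and 421.9 in replicate 2. Peaks near atx-2, the worm ataxin-2 gene, had signals of 149.3 and 181.7, and those near rpl-3, a ribosomal protein gene, 139.7 and 146.8. Of the 754 strongest replicate 1 peaks, 519 (68.8%) overlapped one of the 754 strongest replicate 2 peaks, against a mean of 1.86% and a maximum of 3.32% after relocation (one-sided permutation p = 0.001, the smallest that 1000 relocations can give). With summits required to lie within 100 bp, 57.7% were shared. Among IDR peaks, 511 (67.8%) overlapped one of these strongest peaks in both replicates. Across the 753 IDR peaks matched in both lists, signal was correlated with Spearman's rho = 0.599 and Pearson's r = 0.709 on log2 values (permutation p = 1e-05, the smallest that 100000 permutations can give). Some IDR peaks overlap each other, and the 754 merge to 708 regions; with each pair of replicate peaks counted once, over 707 pairs, rho was 0.563 and r 0.667 (permutation p = 1e-05). This correlation is across peaks, which are not independent replicates, and the IDR list was itself selected on both libraries.

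**Figure D1:**
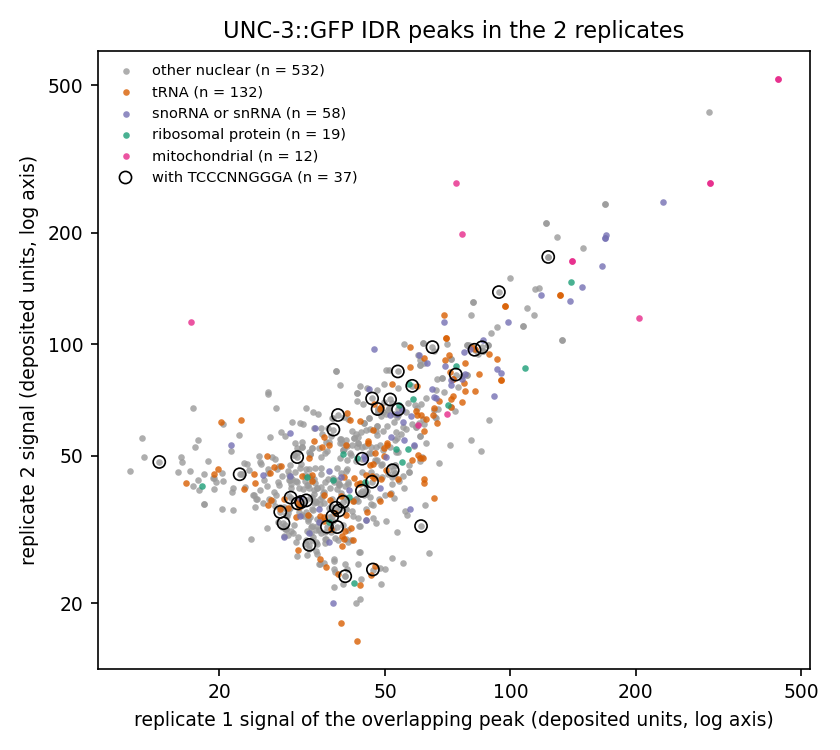
Signal of the strongest overlapping peak in replicate 1 (x axis) and replicate 2 (y axis) for the 753 IDR peaks matched in both lists, in the deposited signal units on log axes, coloured by kind of locus; circles mark the 37 peaks with the COE palindrome. The values rise together (Spearman's rho = 0.599), and mitochondrial peaks are among those farthest apart.

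The next question was which loci carried the strongest signal. Among the 25 strongest IDR peaks, 7 lay on mitochondrial DNA, 7 within 200 bp of snoRNA or snRNA genes, 1 beside a tRNA gene, 1 in the window of a ribosomal protein gene and 9 at other nuclear loci. The 9 other loci were near K12H4.5 (signal 724.9, chromosome III, 8043746 to 8044176, intergenic), ftt-2, which encodes a 14-3-3 protein (405.3, X, 11605791 to 11606380, intergenic), atx-2 (331.9), the splicing regulator gene mbl-1 (330.3, in an intron), M01F1.9 (326.2), C09F5.3 (290.8), ears-2 (261.2), tasp-1 (248.4) and snx-13 (247.5). Small nucleolar RNA genes, whose products guide the modification of ribosomal RNA, accounted for the peaks near F55C5.17 (474.9, chromosome V, 12303468 to 12303804, in an intron), sre-23 (370.6), W03C9.1 (362.4), str-56 (332.3), pxn-1 (298.4), T02E1.2 (274.4) and Y43F8C.7 (250.7). The tRNA peak was nearest to C04A11.5 (267.1, X, 13665454 to 13665688), and the ribosomal protein gene was rpl-3 (286.7, chromosome III, 3867461 to 3867734, intergenic). On mitochondrial DNA the strongest summit of the whole list, with a signal of 996.8, lay at position 12421.

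Small RNA genes recurred throughout the list, a comparison chosen after the data were seen. Of the 741 nuclear IDR peaks, 132 (17.8%, 95% CI 15.1 to 20.8%) had a summit within 200 bp of a tRNA gene, against a mean of 2.15 and a maximum of 8 after relocation (permutation p = 0.001, the smallest possible). For snoRNA or snRNA genes the number was 59 (7.96%, 95% CI 6.12 to 10.2%), against a mean of 1.81 and a maximum of 6 (permutation p = 0.001). Peaks lay at 136 of 612 nuclear tRNA genes (22.2%), 51 of 346 snoRNA genes (14.7%) and 8 snRNA genes (6.20% of those annotated). With the summit required to lie inside the gene, 78 peaks remained for tRNA and 5 for snoRNA or snRNA genes. Of the tRNA genes, 276 (45.1%) are on the X chromosome.

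**Figure D2:**
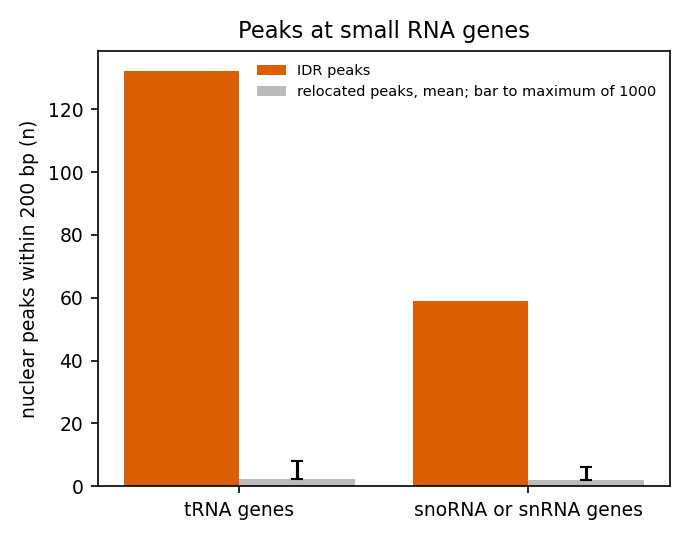
Number of nuclear IDR peaks (y axis) with a summit within 200 bp of tRNA genes and of snoRNA or snRNA genes, observed (orange) and after 1000 random relocations (grey, mean, with a line to the maximum). Observed numbers of 132 and 59 exceeded maxima of 8 and 6.

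Along the chromosomes, the IDR list held 159 peaks on X, 142 on III, 134 on I, 105 on IV, 102 on V, 99 on II and 13 on mitochondrial DNA. Chromosome III had the highest nuclear density, 10.3 peaks per Mb, and chromosome V the lowest, 4.88. The X chromosome carried 21.5% of the nuclear peaks (95% CI 18.6 to 24.6%), above its 17.7% share of nuclear length (exact binomial p = 0.00804). Among the 132 peaks near tRNA genes 65 were on X. Without those peaks the X share was 94 of 609, or 15.4% (exact binomial p = 0.152), so no difference from the share of length was detected. None of the 58 snoRNA or snRNA peaks lay on X, and 93 of the 532 peaks at other nuclear loci did.

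Peaks were concentrated near gene starts. Of the 754 summits, 342 (45.4%) lay in a promoter, against a mean of 14.4% and a maximum of 18.7% after relocation (two-sided permutation p = 0.002, the smallest possible). Nuclear summits were intergenic in 505 of 741 cases (68.2%), in introns of protein-coding genes in 204 (27.5%), in untranslated regions in 25 (3.37%) and in coding sequence in 7 (0.945%). Relocated nuclear peaks fell in coding sequence in 24.7% of cases and between genes in 37.6%.

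The binding site of the COE family, the palindrome TCCCNNGGGA, was then searched at the summits. It was present at 37 of 754 (4.91%, 95% CI 3.48 to 6.70%), against 0.265% of the windows 1000 bp to either side (exact McNemar p = 2.84e-09). With 1 mismatch allowed, 87 peaks (11.5%) carried it, against 2.19% of the flanking windows. The 3 palindromes made by moving the T within each arm occurred in 0.088% of summit windows on average. Within the 100 bp searched on either side, the median distance between palindrome centre and summit was 25.5 bp, and 32 of 37 were within 50 bp. The search itself limits these distances, and they were not compared with random placement. No difference in this share with peak strength was detected: it was 18 of 377 (4.77%) above the median signal and 19 of 377 (5.04%) at or below it (Fisher's exact p = 1.0).

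The palindrome was unevenly spread over the kinds of locus. All 37 peaks with it were among the 532 nuclear peaks (6.95%, 95% CI 4.94 to 9.46%) away from small RNA and ribosomal protein genes, and none was among 132 tRNA peaks (upper 95% limit 2.76%), 58 snoRNA or snRNA peaks (6.16%), 19 ribosomal protein peaks (17.6%) or 13 mitochondrial peaks (24.7%). Ribosomal protein and mitochondrial peaks were too few for a share of 6.95% to be excluded. Of the 37, 18 lay in introns, 17 between genes and 2 in coding sequence, and 6 (16.2%) were in promoters, compared with 279 of 495 (56.4%) of the remaining peaks at other nuclear loci.

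**Figure D3:**
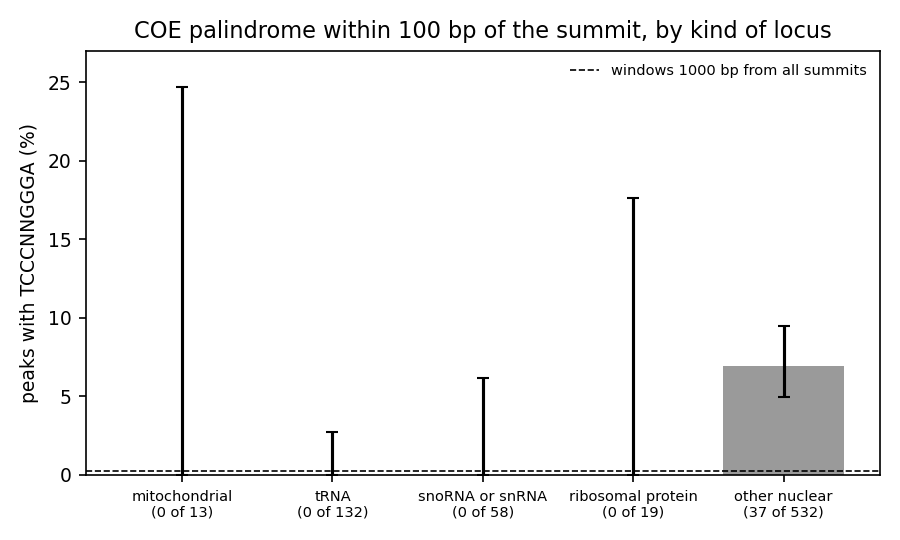
Share of IDR peaks with TCCCNNGGGA within 100 bp of the summit (y axis, percent) for each kind of locus (x axis, with counts), with exact 95% intervals; the dashed line is the 0.265% found in windows 1000 bp away. Only the peaks at other nuclear loci carried the palindrome, at 6.95%.

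Among peaks with the palindrome, named after their values were seen, the strongest were near C09F5.3 (TCCCATGGGA, chromosome III, 665333 to 665342, signal 290.8), egl-27, which encodes a chromatin factor (TCCCCTGGGA, II, 6838455 to 6838464, in an intron, 229.5), and let-526, which encodes a SWI/SNF subunit (181.0, in an intron). Others were nearest to the synaptotagmin genes snt-3 (TCCCAAGGGA, signal rank 163, in coding sequence) and snt-1 (TCCCTAGGGA, II, 6812688 to 6812697, in an intron, 95.2) and to unc-2, which encodes a neuronal calcium channel subunit (TCCCAAGGGA, X, 2728455 to 2728464, 78.5). A further peak lay in the locus shared by cha-1 and unc-17, which encode choline acetyltransferase and the vesicular acetylcholine transporter, the genes that define a cholinergic neuron. This peak (chromosome IV, 3621683 to 3622162, signal 75.5, rank 468) had signals of 30.7 in replicate 1 and 49.6 in replicate 2. Its palindrome, at 3621926 to 3621935, stood in the intronic sequence TCCCCGCCTGTCCCAGGGGACACCGAAAGG, and the summit of the peak, at 3621923, was 2774 bp downstream of the nearest cha-1 TSS.

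**Figure D4:**
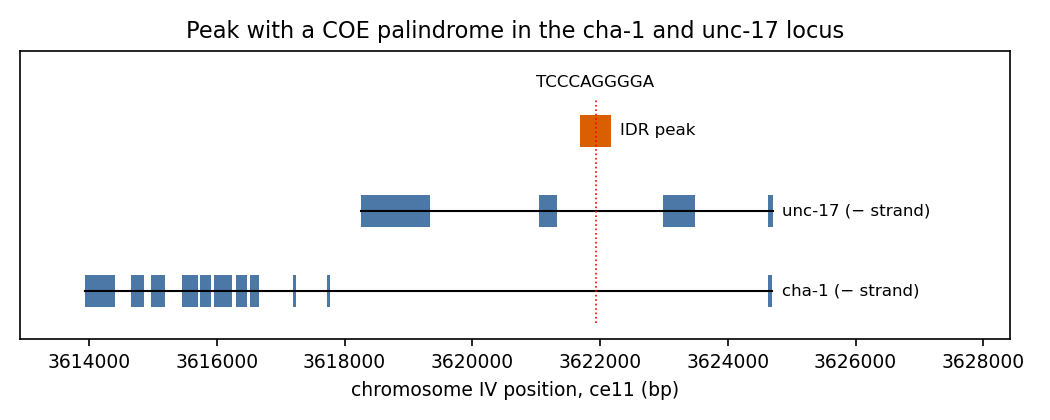
Map of the cha-1 and unc-17 locus on chromosome IV (x axis, ce11 position in bp), with exons as blue boxes, the IDR peak as an orange box and the palindrome as a dotted line. The peak, from 3621683 to 3622162, lies in introns of both genes, away from their shared start.

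Gene lists were used to ask which groups of genes carried peaks near their starts. Ribosomal protein genes had the highest share in these windows, with peaks at 21 of 78 (26.9%, 95% CI 17.5 to 38.2%) against 3.62% of other protein-coding genes (odds ratio 9.82, Fisher's exact p = 5.05e-13, adjusted p = 9.09e-12), among them rpl-3 (signal 286.7), rpl-15 (194.2), rps-28 (160.7) and rps-16 (139.8). The rps-16 peak was nearest to the TSS of fib-1, and rpl-39 and rps-30 shared a peak (80.3). The 21 genes therefore do not stand for separate peaks that all lie nearest to a ribosomal protein gene. When each peak was assigned to the nearest TSS instead, the share of ribosomal protein genes was 16.7% (Fisher's exact adjusted p = 4.45e-05), below the panneuronal share. Panneuronal genes had peaks at 3 of 26 (11.5%, 95% CI 2.45 to 30.2%), those of unc-44, the ankyrin gene (74.1), egl-3, a neuropeptide-processing enzyme gene (72.2), and unc-104, the kinesin-3 gene (71.2), which did not pass the test (Fisher's exact p = 0.0702, adjusted p = 0.631). That call depended on the setting, since by the same exact test replicate 2 alone gave 19.2% (adjusted p = 0.0207), nearest genes at any distance 26.9% (adjusted p = 0.000189), and a window from 1000 bp upstream 0%. Histone genes had peaks at 4 of 50 (8.0%, Fisher's exact adjusted p = 0.682), at the pairs his-35 and his-37 (98.0) and his-67 and his-68 (97.5). Neuropeptide genes had peaks at 4 of 102 (3.92%, Fisher's exact adjusted p = 1.0), namely nlp-76 (175.6), flp-23, nlp-57 (65.0) and nlp-9 (62.1). The nlp-76 and flp-23 peaks are among those within 200 bp of a tRNA gene. Ciliated sensory neuron genes had a peak at 1 of 21 (4.76%, Fisher's exact adjusted p = 1.0), che-13 (113.2), and this peak lay within 200 bp of a snoRNA gene.

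The listed cholinergic genes had no IDR peak in their windows. The counts were 0 of 7 transmission genes (upper 95% limit 41.0%), including cha-1, unc-17 and the choline transporter gene cho-1, 0 of 21 motor neuron effectors (16.1%), including acr-2, del-1 and unc-129, 0 of 29 acetylcholine receptor genes (11.9%) and 0 of 15 motor neuron transcription factor genes (21.8%), against 3.71% of other genes (Fisher's exact adjusted p = 1.0 for each). These limits lie above the background share, so fewer peaks than at other genes could not be shown. The lists do not hold every cholinergic gene. The acetylcholine-gated chloride channel gene acc-4 was on none of them. A peak with the palindrome TCCCCGGGGA (signal 67.4, rank 592), named after its values were seen, lay 470 bp upstream of the acc-4 TSS. No IDR peak lay in the windows of 6 Hox genes, 10 GABAergic, 18 glutamatergic, 15 monoaminergic, 23 body wall muscle, 8 pharynx, 20 intestine, 18 epidermis or 14 germline genes (Fisher's exact adjusted p = 1.0 for each). Outside the windows, peaks had their nearest TSS at 1 gene each of the GABAergic (gab-1), monoaminergic (cat-1, in an intron, beside a tRNA gene), body wall muscle (lev-11) and epidermis (elt-1) lists, and none of these lists passed the test by nearest TSS. The cholinergic and panneuronal lists share ida-1, which had no IDR peak in its window.

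**Figure D5:**
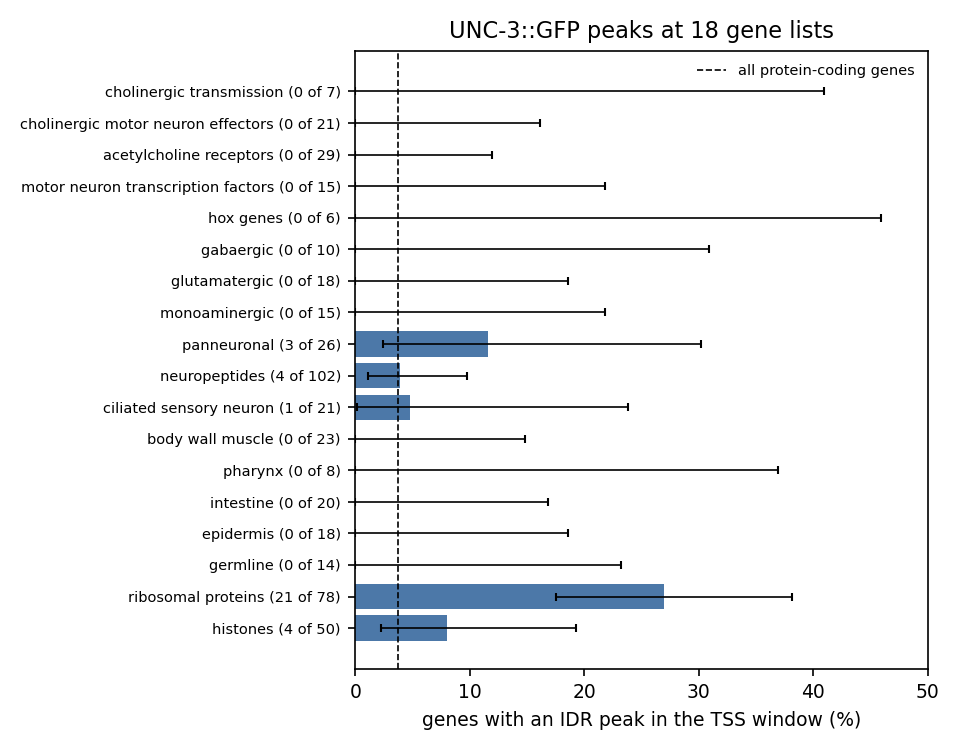
Share of genes with an IDR peak from 2000 bp upstream to 500 bp downstream of a TSS (x axis, percent) for 18 gene lists (y axis, with counts) with exact 95% intervals; the dashed line is the 3.71% of all protein-coding genes. Ribosomal protein genes, at 26.9%, are the only list whose interval lies above the line.

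The gene of the tagged protein and the marker of the strain were examined separately. At unc-3 (X, 14773538 to 14783568) none of the IDR, pooled or replicate lists had a summit in the gene or the 2000 bp upstream of it, and 2 IDR peaks lay within 50 kb, the stronger at 14819010 with a signal of 107.7. At unc-119 (chromosome III, 10902641 to 10908935) no IDR peak lay in the gene or the 2000 bp upstream, while the pooled list had 5 peaks there, the strongest with a signal of 39.4 at rank 1984. Within 50 kb of unc-119 there were 2 IDR peaks, the stronger with a signal of 83.6.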

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

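The tests of the palindrome, of the gene window and of the cholinergic genes in this part were chosen after the results they bear on were seen.

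Signal outside the thresholded list was the first point. Of 14761 pooled peaks below the IDR threshold, 89 (0.603%, 95% CI 0.484 to 0.741%) carried the COE palindrome, against 0.122% of windows 1000 bp away (exact McNemar p = 5.63e-14). The share fell with rank, from 1.88% at ranks 755 to 1500 and 1.47% up to rank 3000 to 0.308% in the weakest 5515 peaks.

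Mitochondrial DNA held 16 pooled peaks, 13 of them in the IDR list, in a genome of 13794 bp, although the tagged protein is a nuclear factor.

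The absence of IDR peaks in the windows of the listed cholinergic genes was weighed against explanations from the processing. Only 3.71% of other genes had such a peak, so lists of 7 and 21 genes can lack one by chance. Peaks with the palindrome lay in the window of a protein-coding gene less often than other peaks at the same kind of locus, 13 of 37 against 372 of 495 (Fisher's exact p = 1e-06), so this window may miss such sites, as it does the peak in the cha-1 and unc-17 locus. Assigning peaks to the nearest TSS at any distance added only cha-1, at 1 of 7 transmission genes. The choice of cha-1 over unc-17 rests on nearly equal starts, at 3624697 and 3624699, and the peak lies in both genes. By that rule the counts stayed at 0 of 21 motor neuron effectors, 0 of 29 acetylcholine receptor genes and 0 of 15 motor neuron transcription factor genes. Palindromes among 0.603% of the peaks below the threshold are consistent with weaker sites having been left out. Whether cholinergic genes are among them could not be decided, since 15 of 28 genes of both cholinergic lists (53.6%) had a peak of the whole pooled list in the window against 37.8% of other genes (Fisher's exact p = 0.12). No biological explanation was tested, as there is 1 group, and dilution of the few cholinergic neurons in whole embryos stays open.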

How the results depend on the processing

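Of 95 alternative values for 14 results, 78 kept the direction and the side of the threshold, or stayed within 1.5 times for a count. The analyses of the whole pooled list, of nuclear peaks alone, of replicate peak pairs counted once, of tRNA distance and of snoRNA or snRNA genes were chosen after seeing the data. Without peaks within 200 bp of a tRNA gene the X share was 15.4%, below the X share of length but not different from it by the test (exact binomial p = 0.152). Of the 132 removed peaks, 65 were on X. The difference in palindrome share between stronger and weaker peaks, -0.265 points, turned to 0.0199 points for peaks shared with both replicates, 0.265 points in either replicate alone, 0.265 with 1 mismatch and 0.265 within 50 bp, and none of these passed the test. Panneuronal genes with a peak made up 0% in the stricter list, 0% with the window from 1000 bp upstream, 26.9% by nearest TSS, 84.6% with the whole pooled list, and 11.5 to 19.2% with each replicate left out; the cause was not tested. Cholinergic transmission genes reached 14.3% by nearest TSS, from the peak in the cha-1 and unc-17 locus, which was assigned to cha-1. They reached 57.1% with the whole pooled list, and motor neuron effectors 52.4% there, none past the test. Enriched lists numbered 1, but 2 by nearest TSS, 2 with the whole pooled list, and 1 to 2 with each replicate left out. Ribosomal protein genes fell from 26.9% to 16.7% by nearest TSS, still past the test. Every alternative of the replicate overlap, the replicate correlation, the promoter share, the palindrome share, the ribosomal protein list and the tRNA and snoRNA or snRNA shares kept its direction and call. Leaving out a replicate was not possible for the overlap and the correlation. Read depth is unknown, so what it limits could not be assessed.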

Other observations

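The tests in this part were chosen after the results they bear on were seen, except that of strongly transcribed genes, which was stated before its own result was seen, and the gene lists, which were fixed before the data were examined.

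With the whole pooled list, background included, panneuronal genes had peaks in their windows at 22 of 26 (84.6%) against 37.7% of other genes (Fisher's exact adjusted p = 1.11e-05), and ribosomal protein genes at 69 of 78 (88.5%, adjusted p = 2.85e-19). No other list of the 18 passed the test, though body wall muscle genes fell just short, at 15 of 23 (65.2%, Fisher's exact adjusted p = 0.0537). Genes with more TSSs have more windows in which a peak can fall. Neither the number of TSSs nor gene length was accounted for in these shares. Among the motor neuron effectors, the strongest pooled peaks in the windows were those of ida-1, which is also on the panneuronal list (signal 47.2), del-1 (42.4) and acr-14 (37.5), all below the IDR threshold.

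Seen from the genome, 390 exact COE palindromes occur on the nuclear chromosomes. Summit windows of IDR peaks covered 39 of them (95% CI of the share 7.21 to 13.4%), and those of the pooled list 128 (32.8%, 95% CI 28.2 to 37.7%). Palindromes with the T moved were covered by pooled summit windows at 25 of 725 (3.45%), 12 of 642 (1.87%) and 11 of 136 (8.09%) sites.

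A hypothesis for the peaks with the COE palindrome is that their nearest genes are neuronal more often than those of other peaks, which may hold here. Their nearest genes belonged to the 254 genes of the 10 neuronal lists (cholinergic transmission, motor neuron effectors, acetylcholine receptors, motor neuron transcription factors, GABAergic, glutamatergic, monoaminergic, panneuronal, neuropeptide and ciliated sensory neuron genes) in 4 of 37 cases (10.8%), cha-1, snt-1, unc-2 and gab-1. Among the 495 other peaks at the same kind of locus this held for 9 (1.82%; Fisher's exact p = 0.009). These genes had been seen beside the palindrome before the test was chosen, so the p-value is not independent evidence, and long introns and intergenic regions of neuronal genes were not accounted for.

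Peaks at tRNA, snoRNA, snRNA and ribosomal protein genes formed a group of 209. Binding directed by the exact COE palindrome was argued against at tRNA genes, where 0 of 132 peaks carried it against 37 of 532 other nuclear peaks (Fisher's exact p = 0.00041), less firmly at snoRNA and snRNA genes (0 of 58, p = 0.04), and stays open at ribosomal protein genes (0 of 19, p = 0.63). These p-values were not adjusted. Palindromes with a mismatch were not compared between kinds of locus, so binding at such sites stays open. Recovery of strongly transcribed loci without sequence-specific binding is a candidate explanation: of 41 other genes listed as strongly transcribed, 8 had a peak (19.5% against 3.58% of other genes; Fisher's exact p = 9.3e-05), namely atp-1, cct-7, cct-8, hsp-1, hsp-90, tba-1, tba-2 and tbb-2. Strong transcription of these 41 genes was assumed, as no expression data were used. The share shows only that these genes had peaks more often. With the control not analysed, it cannot tell whether binding there was sequence-specific. Reads shared between identical tRNA copies may contribute, since 0 of 25 tRNA genes made only of unique 36-mers had a peak against 136 of 587 others, and genes with a whole sequence of their own had peaks less often than genes with copies, 17 of 143 (11.9%) against 25.4% of 469 (Fisher's exact p = 0.00053). Those 17 exceed the maximum of 4 after relocation. However, a summit within 200 bp was enough, and some summits were shared by neighbouring tRNA genes. Peaks owed to a neighbouring gene were not separated. The 17 therefore do not decide whether sharing over the whole gene length was the sole cause. Whether genes of unique sequence are transcribed less was not tested.

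The excess of peaks on the X chromosome may follow from tRNA genes, which are concentrated there. Away from tRNA genes 15.4% of nuclear peaks were on X, not above the 17.7% share of length, while 48.5% of the tRNA peaks were on X. No biological explanation was tested.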
